A study of Mus musculus with 8 samples.

How the data were processed

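The data are RNA-seq counts from the kidneys of MRL-lpr mice, a lupus-prone strain that carries a mutation of the death receptor gene Fas. Per the labels, 4 mice served as controls and 4 received propionate, a short-chain fatty acid made by gut bacteria, at 200 mM in the drinking water for 6 weeks. Tissue was taken at 12 weeks of age, RNA was purified on columns, and paired reads of 150 bases were sequenced on an Illumina instrument, per the labels' protocols. The library kit, its strandedness, the sex of the mice, litters and batches are not given in the sources used here. The group of each library was taken from its treatment label, and the columns of the table were matched through the sample identifiers in the labels. The replicate numbers in the titles were taken only as names.

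One table was analysed, with 1931 genes. The authors deposited whole-number read counts per gene, the same counts divided by 1 size factor per library (a scaled signal per gene), group means of these scaled counts, and FPKM, per the file headers. The deposited log2 fold changes, p-values and adjusted p-values are the authors' own. DESeq2 and the genome build mm10 are named in the submitters' processing notes, without a DESeq2 version. The aligner and the read counter are not given in the sources used here. The largest deposited unadjusted p in the authors' deposited table is 0.05 after rounding, so the genes listed had been selected for a difference on these same libraries. Genes outside the selection are not analysed here, and nothing can be said of their levels. The deposited adjusted p-values follow from the deposited p-values if 16064 genes entered the adjustment. With that number they were recovered to a relative error of 4.03e-06. An adjusted p of 1 is listed for 135 low-count genes.

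Gene positions were compared with the GENCODE M21 annotation of GRCm38. Of the gene identifiers, 1913 were in that annotation and 18 were not. Of the shared identifiers, 44 had the same start and end. The coordinates therefore differ from those of the build in the submitters' notes, and the build they follow is not given in the sources used here. Coordinates are printed as the table gives them.

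Library totals were recovered from counts, FPKM and gene length, since each library gave 1 total for all genes. They ranged from 20005328 to 26711127 assigned reads. The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 on the deposited counts, with these totals, TMM factors and the default expression filter of edgeR. It tested 1792 genes. TMM factors and dispersions came from these selected genes alone. TMM takes most genes to be unchanged, which genes selected for a difference need not meet, so the log2 fold changes and their directions carry that uncertainty. Benjamini-Hochberg adjustment was made over these genes, as fixed before the data were examined for the case of a preselected table. Since each gene had already passed an unadjusted test, such an adjustment passes most of them by construction. A second adjustment over all 16064 genes was added after the data were examined, with the genes not analysed here taken to have larger p-values. Each model used 4 libraries per group and no covariate.

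The 45 gene lists (pathways, kidney cell types, immune cells, signs of tissue quality) were written before the data were examined. For each list with at least 5 tested members, Fisher's exact test, two-sided, compared members higher and lower with the rest of the tested genes. These p-values were adjusted over 10 lists. The test takes genes as independent, which they are not, so camera with a preset correlation of 0.01, camera with an estimated correlation, and fry (limma 3.58.1) were run beside it. List scores are means of centred log2 values and were compared by exact permutation of the 8 libraries, two-sided, for which the smallest possible p is 0.0286. Another 4 lists were written after the table had been examined, with many members picked once their direction had been seen, and the result of 1 of them is not reported here.

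The genes named follow a rule fixed before the data were examined. It takes the 8 largest differences in each direction among protein-coding genes past an adjusted p of 0.05 over the listed genes, with a mean of at least 50 in the higher group and no overlap between groups. It adds the 4 smallest adjusted p-values in each direction, the 3 leading members of lists with a result, up to 2 members of 6 lists chosen in advance, and single genes named in advance. Predicted genes were left out and antigen receptor genes were taken as a group. The rule gave 50 genes. Of the genes named in advance, Fas, Ddx3y, Nphs1, Lcn2 and Havcr1 are not among the genes in the table. Other genes are said to have been chosen after their values were seen.

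The edgeR steps were tested on simulated data with the real means and totals and 1792 genes. Of these, 50 were changed at each ratio given below and 1592 were left unchanged. The simulated genes had not been selected for a difference, while their dispersions came from the real genes, which had been. The shares called therefore describe the steps and not the genes analysed here. Over the simulated genes, 46% of those changed in a ratio of 5 to 4, 82% of those changed 1.5-fold, 96% changed 2-fold and 94% changed 3-fold were called, and 0.691% of unchanged genes. With the adjustment over 16064 genes, the shares for the changed genes were 24%, 62%, 84% and 90%. The test of lists called any of 10 random lists in 2 of 100 simulated draws. These lists were drawn gene by gene, so this does not give the false call rate of lists whose members move together. A seeded list of 32 genes, 31 of them higher, was recovered in all 100 draws, which its make-up fixed in advance. The common dispersion was 0.015. In a comparison of the counts of each pair of libraries, the lowest chi-square per degree of freedom was 9.1, so no library was a duplicate of another. The alternatives were other scalings, filters, tests and thresholds, the replicate number as a block, each library left out in turn, subsets of genes, and removal of a gene length and GC trend. That trend was fitted in each library on the deposited gene length and on the GC content of the longest transcript in GENCODE M21. Values are size-factor-scaled counts as deposited, mean ± SD with n = 4, and log2 fold changes are propionate over control from edgeR, ± SE.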

Results

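Kidney transcripts were counted in 8 MRL-lpr mice, 4 controls and 4 given propionate in the drinking water, to ask how this bacterial metabolite acts in lupus. The control libraries held 25613108, 26002214, 24091251 and 20005328 assigned reads and the propionate libraries 25116113, 24608712, 26711127 and 24776023. The genes analysed made up 13.4% to 15.1% of the reads. They had been selected by the authors for an unadjusted difference between these same libraries, 983 higher and 948 lower with propionate. If no gene differed, about 803 genes would still be expected to pass such an unadjusted selection. That is 44.7% of the 1796 listed genes under the authors' adjustment. Many of the listed genes may therefore not differ, and the list cannot show what stayed the same.

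With propionate, kidneys had lower levels of Pck1 and Lpl. Pck1, the enzyme that commits oxaloacetate to gluconeogenesis, went from 27124 ± 2295 to 15322 ± 2996 scaled counts (SD, n = 4), a log2 fold change of -0.87 ± 0.13 (SE). Lpl, the lipase that frees fatty acids from circulating lipoproteins, went from 15358 ± 959 to 10428 ± 930 (SD, n = 4), a log2 fold change of -0.60 ± 0.07 (SE), and its call ended once a gene length and GC trend was removed (-0.19, edgeR adjusted p = 0.151 over the listed genes). Among higher transcripts, Slc6a19, the main neutral amino acid transporter of the proximal tubule brush border, went from 5666 ± 1109 to 8550 ± 868 (SD, n = 4), a log2 fold change of 0.55 ± 0.13 (SE). Ribosomal protein transcripts were higher by a smaller amount, with 32 of 32 tested members in that direction (Fisher's exact test, adjusted p = 2.12e-08), which did not pass by camera with an estimated correlation (adjusted p = 0.599). Without control replicate 3, Slc6a19 had a log2 fold change of 0.54 and an edgeR adjusted p of 0.051 over the listed genes.

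Adjusted over all genes, 157 genes differed at an adjusted p of 0.05 in the authors' deposited table, of which 54 rose and 103 fell. The median absolute log2 fold change of these genes in the authors' deposited table was 0.43, and 19 of them reached 1. In 147 of them the libraries of the groups did not overlap, which their selection on these same libraries favours. Selection on these same libraries favours low p-values by edgeR too. Of 1792 tested genes, 1463 had an unadjusted p under 0.05 by edgeR. Of the 1792, 1216 passed the adjustment over the listed genes, 465 higher and 751 lower. The share higher among them was 38.2% with TMM and 53.4% with the authors' size factors, and once a gene length and GC trend was removed it was 70.8% (408 higher and 168 lower). The median log2 fold change of all tested genes was 0.11 with TMM and 0.16 with the authors' size factors. The balance of directions therefore depends on the scaling. Adjusted over 16064 genes, edgeR left 6 genes, all lower, where DESeq2 left 172 (61 higher and 111 lower), of which 154 are among the 157, and edgeR with the trend removed left 109 (91 higher and 18 lower). The count of 1216 became 571, 339, 148 and 568 without control replicate 1, 2, 3 and 4, and 197 and 206 without propionate replicate 3 and 4.

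The 6 genes past the edgeR adjustment over 16064 genes were Slc16a4, Akr1c14, Lpl, Nt5e, Map3k7cl and Cyp51. This count became 0 with the authors' size factors, with total-count scaling, with the replicate number as a block, without control replicate 2 or 4 and without propionate replicate 1 or 4. Slc16a4, a member of the monocarboxylate transporter family, went from 3254 ± 177 to 2214 ± 137 (SD, n = 4), a log2 fold change of -0.60 ± 0.06 (SE) with an edgeR adjusted p of 0.0312. Akr1c14, an aldo-keto reductase of steroid metabolism, went from 2678 ± 424 to 1132 ± 251 (SD, n = 4), a log2 fold change of -1.28 ± 0.16 (SE) with an edgeR adjusted p of 0.0391. The edgeR adjusted p was also 0.0391 for Lpl, for Nt5e, the ecto-enzyme that forms adenosine from AMP (log2 fold change -0.47 ± 0.06, SE), and for Map3k7cl (-0.51 ± 0.06). Cyp51, lanosterol demethylase of cholesterol synthesis, had a log2 fold change of -0.46 ± 0.06 (SE) and an edgeR adjusted p of 0.0424. Nt5e lies outside the naming rule and was chosen after its values were seen. The adjusted p in the authors' deposited table was 1.52e-10 for Slc16a4 and for Akr1c14, 3.55e-08 for Lpl and 7.03e-05 for Cyp51. As the table gives them, Slc16a4 lies on chromosome 3 from 107198546 to 107219431, Akr1c14 on chromosome 13 from 4099011 to 4140688, Lpl on chromosome 8 from 69333143 to 69360100 and Cyp51 on chromosome 5 from 4131145 to 4154746, in a build not given in the sources used here. Once a gene length and GC trend was removed, the call of Cyp51 over the listed genes ended beside that of Lpl (log2 fold change of Cyp51 -0.19, edgeR adjusted p = 0.0996). Slc16a4 then had a log2 fold change of -0.24 (edgeR adjusted p = 0.0424 over the listed genes). Adjusted over 16064 genes these trend-removed p-values would be larger, so they do not show that Slc16a4 passed there.

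**Figure D1:**
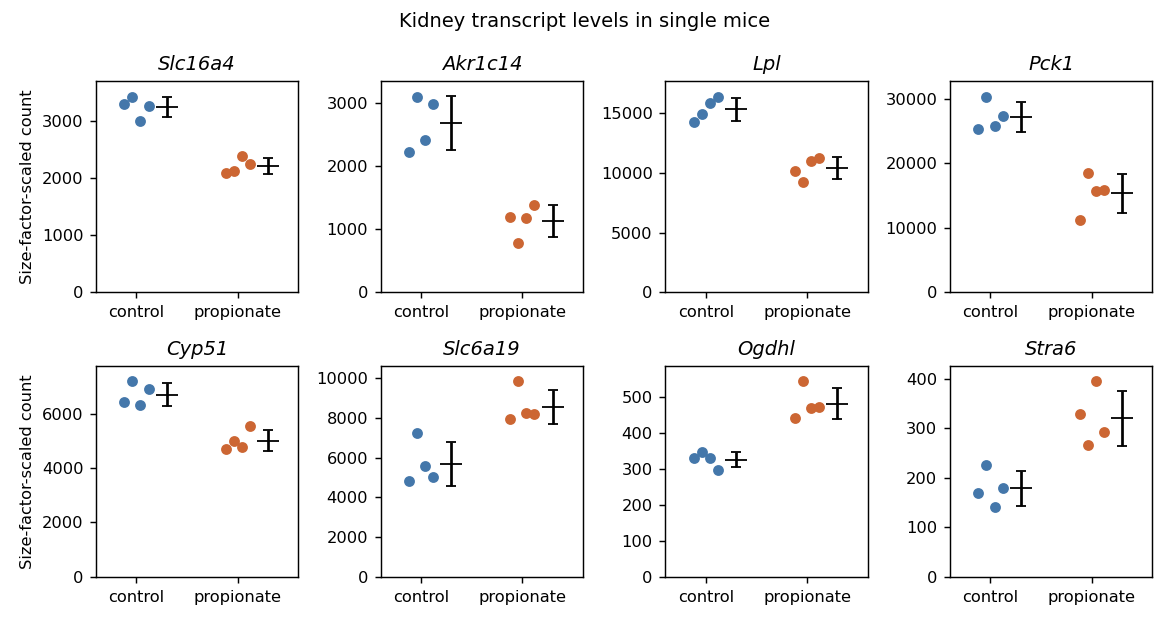
Size-factor-scaled counts of 8 genes in each of 4 control and 4 propionate kidneys, 1 point per mouse, with the group mean and SD beside the points as a bar. The vertical axes start at 0; the groups do not overlap in any of the 8 genes, which had been selected on these libraries.

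Several of the larger rises were in low-count genes. Grem1, an antagonist of bone morphogenetic proteins, went from 17.1 ± 9.71 to 63.1 ± 24.2 scaled counts (SD, n = 4), a log2 fold change of 1.84 ± 0.43 (SE). Stra6, the receptor for retinol-binding protein, had a log2 fold change of 0.80 ± 0.17 (SE), Bex1 0.73 ± 0.17, the secreted hormone Stc1 0.64 ± 0.16 and the peptide hormone Adm2 0.54 ± 0.13. All 5 rose in the authors' deposited table, at adjusted p-values of 0.00711 for Grem1, 0.00143 for Stra6, 0.0337 for Bex1, 0.0172 for Stc1 and 0.0214 for Adm2. Marchf10 (0.90 ± 0.29, SE) and Pde6a (0.63 ± 0.22) were also among the 8 largest differences upward under the naming rule (protein-coding genes with a mean of at least 50 in the higher group and no overlap), and their adjusted p-values in the authors' deposited table were 0.114 and 0.232. The smallest p-values upward were those of Ogdhl (log2 fold change 0.52 ± 0.09, SE), Uap1l1 (0.34 ± 0.05), the growth factor midkine, Mdk (0.46 ± 0.09), and Zfp622 (0.39 ± 0.08). These 4 rose at adjusted p-values of 0.000241, 0.000445, 0.000739 and 0.0032 in the authors' deposited table. Without propionate replicate 3 the edgeR adjusted p over the listed genes was 0.0511 for Grem1 (log2 fold change 1.66), 0.0539 for Stc1 (0.58) and 0.054 for Adm2 (0.47), and without control replicate 3 it was 0.0529 for Bex1 (0.73). The calls of Marchf10 and Pde6a each ended when any 1 of 6 or more libraries was left out, and without propionate replicate 2 the log2 fold change of Marchf10 was 0.59 (edgeR adjusted p = 0.0551). With the length and GC trend removed, the call of Adm2 ended (log2 fold change 0.35, edgeR adjusted p = 0.076), and the log2 fold changes of Mdk, Stc1 and Zfp622 were 0.29, 0.99 and 0.76.

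Downward, the 8 largest differences under the same naming rule, which leaves out larger ones in genes with lower counts or overlapping groups, were those of Itgb2l (log2 fold change -1.61 ± 0.30, SE), Arsi (-1.56 ± 0.34), the myeloid adhesion receptor Adgre4 (-1.55 ± 0.35), Nat8f5 (-1.29 ± 0.27), Akr1c14, the chemokine Ccl28 (-1.22 ± 0.29), the mitochondrial copper chaperone Cox17 (-1.19 ± 0.28) and Fos (-1.15 ± 0.32). The adjusted p for Fos in the authors' deposited table was 0.0743, so its difference did not pass. The other 7 fell, at adjusted p-values in the authors' deposited table of 0.000631 for Itgb2l, 0.00704 for Arsi, 0.0177 for Adgre4, 0.00298 for Nat8f5, 0.00889 for Ccl28 and 0.031 for Cox17, beside that of Akr1c14. By edgeR over the listed genes, the calls of Ccl28 and Fos ended without control replicate 3 (log2 fold changes -1.20 and -0.96, adjusted p = 0.0516 and 0.0631) and without propionate replicate 3 (-1.14 and -1.23, adjusted p = 0.0511 and 0.0534). Those of Cox17 and Fos ended without propionate replicate 4 (-1.05 and -0.96, adjusted p = 0.0508 and 0.058), and that of Cox17 without propionate replicate 3 (-1.08, adjusted p = 0.0508). Nat8f5 and Akr1c14 belong to families of close copies, and how reads shared between copies were counted is not given in the sources used here.

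Of the 45 gene lists, 10 had at least 5 tested members, 24 had 1 to 4 and 11 had none in the table. Those with none were the lists for interferon-gamma response, antigen presentation by MHC class II, B cells, plasma cells and immunoglobulin, T and NK cells, extracellular matrix and fibrosis, tubular injury, cell cycle, histones, adipose tissue and adrenal gland. Tested members were 32 of 51 symbols for ribosomal proteins, 13 of 46 for oxidative phosphorylation and 12 of 43 for PPAR-alpha and fatty acid oxidation. They were 8 of 31 for cholesterol and fatty acid synthesis, 17 of 43 for proximal tubule and 5 of 36 for macrophages and dendritic cells. The other symbols were not tested, so counts of members do not describe a whole pathway or cell type. In 2 lists the direction of the members differed from that of the rest of the table by Fisher's exact test. Neither passed by camera with an estimated correlation (adjusted p = 0.599 for both).

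Ribosomal protein genes were higher in 32 of 32 tested members, against 53.2% of all tested genes (Fisher's exact test, adjusted p = 2.12e-08). With an estimated correlation between genes, camera gave an adjusted p of 0.599. With the length and GC trend removed, 30 of 32 were higher (Fisher's exact test, adjusted p = 0.00128), and camera with an estimated correlation gave an adjusted p of 0.64. Of the 32, 19 passed the edgeR adjustment over the listed genes, where 1216 of all 1792 tested genes did, and 19 passed when adjusted over the list alone. Rplp0 went from 7762 ± 183 to 8918 ± 376 (SD, n = 4), a log2 fold change of 0.16 ± 0.04 (SE), and was the 1 member that rose in the authors' deposited table (adjusted p = 0.0259). Rpl19 had a log2 fold change of 0.21 ± 0.05 (SE) and Rpl8 of 0.26 ± 0.07. Once the length and GC trend was removed these became 0.10 for Rplp0, 0.08 for Rpl19 and 0.07 for Rpl8, with edgeR adjusted p-values of 0.12, 0.235 and 0.308. All 3 calls also ended without control replicate 3 (log2 fold changes 0.17, 0.23 and 0.26) and without propionate replicate 3 (0.17, 0.22 and 0.27), at edgeR adjusted p-values of 0.0529 to 0.0615. Ribosomal protein genes have many near-identical pseudogenes, so their counts are uncertain.

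Nuclear-encoded genes of oxidative phosphorylation, the mitochondrial respiratory chain and ATP synthase, were higher in 13 of 13 tested members (Fisher's exact test, adjusted p = 0.00157). The camera adjusted p was 0.599 with an estimated correlation, and 0 members passed in the authors' deposited table. By edgeR 3 passed over the listed genes, where 1216 of all 1792 tested genes did, and 0 when adjusted over the list alone. The 3 were Ndufb5 (log2 fold change 0.21 ± 0.07, SE), Atp5g1 (0.19 ± 0.07) and Cox7a2 (0.18 ± 0.07). With the length and GC trend removed the list had 12 of 13 members higher and an adjusted p of 0.0792. Ndufb5 then had a log2 fold change of 0.43, Atp5g1 of 0.455 and Cox7a2 of 0.12, and the call of Cox7a2 ended (edgeR adjusted p = 0.153). Each of the 3 calls also ended when any 1 of 5 or more libraries was left out. Of the 4 mitochondrially encoded genes tested, named after their values were seen, 2 were higher and 2 lower. The subunits mt-Nd5 (log2 fold change -0.26 ± 0.11, SE) and mt-Nd4l (-0.68 ± 0.26) were lower. The ribosomal RNAs mt-Rnr1 (0.24 ± 0.13) and mt-Rnr2 (0.30 ± 0.12) were higher. None of the 4 passed in the authors' deposited table.

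**Figure D2:**
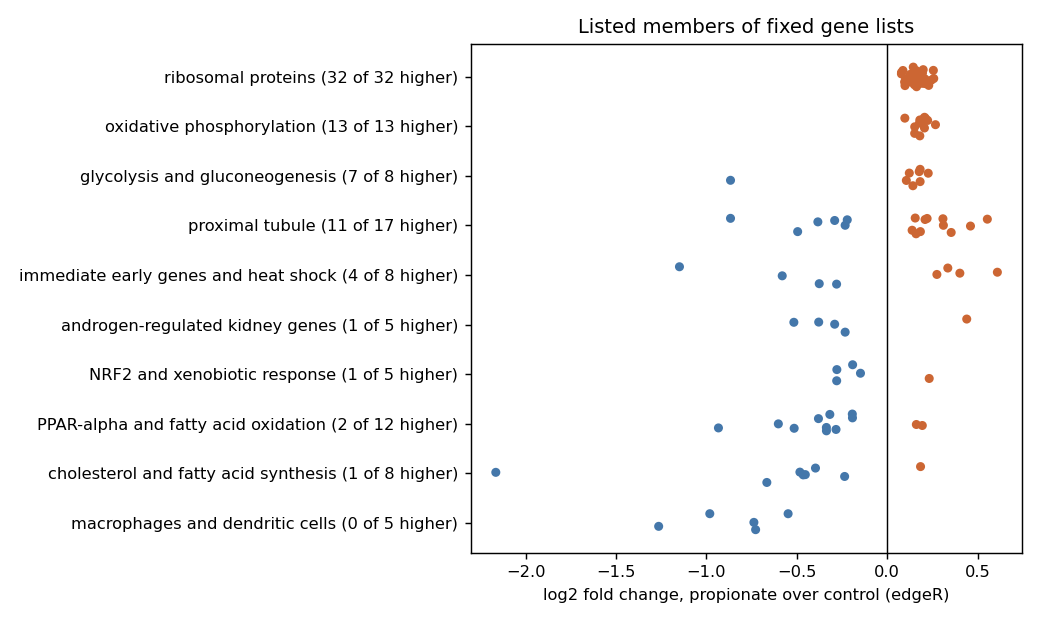
Log2 fold changes from edgeR, propionate over control, of the tested members of the 10 lists with at least 5 of them, 1 point per gene, with vertical scatter only to separate points. Ribosomal protein genes (32 of 32) and oxidative phosphorylation genes (13 of 13) all lie above 0; members had been selected on these libraries.

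Genes of PPAR-alpha signalling and fatty acid oxidation were lower in 10 of 12 tested members, and the list missed the threshold (Fisher's exact test, adjusted p = 0.0553). By edgeR 9 members passed over the listed genes, where 1216 of all 1792 tested genes did, and 4 members fell in the authors' deposited table. When adjusted over the list alone all 12 passed, the 2 higher ones included, which their selection on these libraries favours. Cyp4a14, a fatty acid hydroxylase, went from 10707 ± 552 to 7698 ± 1088 (SD, n = 4), a log2 fold change of -0.51 ± 0.10 (SE). Acadm, the medium-chain acyl-CoA dehydrogenase, had a log2 fold change of -0.34 ± 0.07 (SE), and Ehhadh of -0.34 ± 0.08. The adjusted p in the authors' deposited table was 0.000948 for Cyp4a14, 0.0471 for Acadm and 0.0537 for Ehhadh. All 3 calls ended once the length and GC trend was removed (log2 fold changes -0.28, -0.14 and -0.13), while the list then passed, with 9 of 12 members lower where 63.8% of all tested genes, up from 53.2%, were higher (Fisher's exact test, adjusted p = 0.0385). By camera with an estimated correlation its adjusted p was 0.599 before and 0.64 after that removal. Without control replicate 3 and without propionate replicate 4 the call of Ehhadh ended as well (edgeR adjusted p = 0.0543 and 0.0508).

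Genes of cholesterol and fatty acid synthesis were lower in 7 of 8 tested members (adjusted p = 0.0585 by Fisher's exact test, which did not pass). Beside Cyp51, Me1, the malic enzyme that supplies NADPH, fell at an adjusted p of 0.0473 in the authors' deposited table. Its log2 fold change by edgeR was -0.40 ± 0.10 (SE). Scd1, stearoyl-CoA desaturase, went from 34584 ± 9648 to 22527 ± 4517 (SD, n = 4), with overlapping groups. The adjusted p for Scd1 in the authors' deposited table was 0.27, which did not pass. With the length and GC trend removed, Me1 had a log2 fold change of -0.11 (edgeR adjusted p = 0.34) and Scd1 of -0.41 (edgeR adjusted p = 0.142), so that both edgeR calls ended. Without propionate replicate 3 and 4 they ended too, at edgeR adjusted p-values of 0.0534 and 0.051 for Me1 and 0.0592 and 0.051 for Scd1, and that of Scd1 without control replicate 1 and 4 (0.0503 and 0.0521).

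Proximal tubule markers moved both ways, 11 higher and 6 lower of 17 tested (Fisher's exact test, adjusted p = 0.517). Of these, 3 rose and 2 fell in the authors' deposited table. Beside Slc6a19, Spp2 had a log2 fold change of 0.46 ± 0.10 (SE). Slc13a3, the dicarboxylate transporter of the basolateral membrane, had one of -0.38 ± 0.08 and Pck1 is the other that fell. Adjusted p-values in the authors' deposited table were 0.00186 for Slc6a19, 0.00196 for Spp2, 0.0215 for Slc13a3 and 1.18e-06 for Pck1. Glycolysis and gluconeogenesis genes were higher in 7 of 8 members (adjusted p = 0.124 by Fisher's exact test), with Fbp2 (log2 fold change 0.23 ± 0.08, SE) and Pck2 (0.18 ± 0.06) higher and Pck1 the 1 lower. Without genes that stand in more than 1 list, Pck1 among them, 7 of 7 were higher (Fisher's exact test, adjusted p = 0.0378), with an adjusted p of 0.57 by camera with an estimated correlation. The calls of Fbp2 and Pck2 each ended when any 1 of 5 or more libraries was left out, and Pck2 had a log2 fold change of 0.32 with the length and GC trend removed.

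Of the 36 macrophage and dendritic cell markers in the list, 5 were tested and all 5 were lower. The list did not pass (Fisher's exact test, adjusted p = 0.0556), while it did with the length and GC trend removed (the same 5 lower, adjusted p = 0.0309, with more of the other genes higher). By camera with an estimated correlation its adjusted p was 0.599 before and 0.64 after that removal. Cd68 went from 273 ± 102 to 167 ± 76.4 scaled counts and the mannose receptor Mrc1 from 217 ± 52.3 to 134 ± 28 (SD, n = 4). These values were chosen after they were seen, and 0 members passed in the authors' deposited table. Among other lists with 5 or more members, genes of the NRF2 response and androgen-regulated kidney genes were each lower in 4 of 5 (adjusted p = 0.24 by Fisher's exact test for both), and immediate early and heat shock genes in 4 of 8 (adjusted p = 1). Of the last, Zfp36 had a log2 fold change of -0.38 ± 0.11 (SE) and Dnajb1 of 0.40 ± 0.13, and their calls each ended when any 1 of 3 or more libraries was left out.

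Lists with fewer tested members were not tested for direction. Of the listed genes of propionyl-CoA metabolism, Aldh6a1 had a log2 fold change of -0.25 ± 0.10 (SE) and Acss1 of 0.17 ± 0.07. Of the short-chain fatty acid receptors and transporters, the monocarboxylate transporter Slc16a1 had a log2 fold change of -0.35 ± 0.13 (SE) and the sodium-coupled transporter Slc5a8 of -0.32 ± 0.13. Adjusted p-values in the authors' deposited table were 0.372 for Aldh6a1, 0.169 for Acss1, 0.342 for Slc16a1 and 0.372 for Slc5a8, so none of the 4 passed. Aldh6a1 and Slc5a8 turned to 0.12 and 0.06 once the length and GC trend was removed, and Slc16a1 had a log2 fold change of -0.01 (edgeR adjusted p = 0.96). Acss1 kept its call over the listed genes with the trend removed (log2 fold change 0.24, edgeR adjusted p = 0.0269). The edgeR calls of all 4 ended when any 1 of 6 or more libraries was left out. The 1 type I interferon gene in the table, Stat2, had a log2 fold change of -0.32 ± 0.14 (SE) and an edgeR adjusted p of 0.063 over the listed genes. Col4a3, a type IV collagen chain of the glomerular basement membrane made by podocytes, went from 4095 ± 303 to 2881 ± 494 (SD, n = 4), a log2 fold change of -0.54 ± 0.13 (SE). It fell at an adjusted p of 0.00633 in the authors' deposited table, and without control replicate 3 its edgeR adjusted p over the listed genes was 0.0522 (log2 fold change -0.52). Renin, Ren1, had a log2 fold change of 0.49 ± 0.18 (SE), and its adjusted p in the authors' deposited table was 0.132. Its edgeR call ended with the trend removed (log2 fold change 0.39, edgeR adjusted p = 0.0963) and when any 1 of 6 libraries was left out.

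Xist, the transcript of the inactive X chromosome, was counted in all 8 libraries, from 2206 to 6077 scaled counts. Its mean went from 5473 ± 770 to 3397 ± 884 (SD, n = 4), a log2 fold change of -0.72 ± 0.19 (SE), and it fell at an adjusted p of 0.0134 in the authors' deposited table. It is 1 of 21 tested nuclear-retained and intron-retaining transcripts, a list written after the table had been examined, and all 21 were lower. Of 19 immunoglobulin V genes in the table, 13 were lower and 6 higher, and 1 in each direction passed in the authors' deposited table.

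Direction followed gene length and GC content across the tested genes, which are not independent replicates. Genes higher with propionate had a median length of 2923 bases and those lower 5802 bases (permutation p = 0.0001, the smallest that 10000 permutations can give). Median GC content was 54.0% in the higher and 46.4% in the lower genes (permutation p = 0.0001). When the genes were split by length into 5 nearly equal groups, 80.8% were higher in the shortest group and 17.5% in the longest. With the trend removed, the log2 fold change of Xist was -0.28 (edgeR adjusted p = 0.112 over the listed genes), so that its call ended. It also ended without control replicate 3 (-0.67, edgeR adjusted p = 0.0606) and without propionate replicate 3 (-0.70, edgeR adjusted p = 0.0549).

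**Figure D3:**
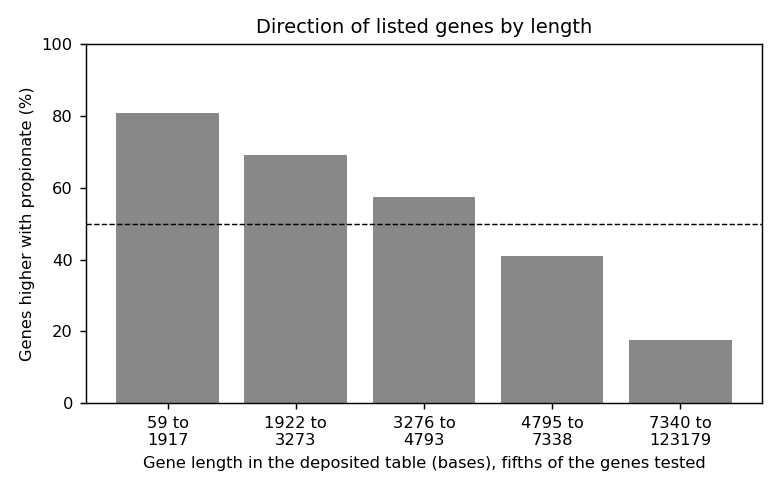
Percent of tested genes higher with propionate in 5 nearly equal groups of gene length, from the shortest on the left to the longest on the right; bars start at 0 and the dashed line marks 50%. The share runs from 80.8% in the shortest to 17.5% in the longest genes.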

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

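The tests on gene length and GC content and on proximal tubule markers, and the reading of the splits of the libraries, were chosen after the results were seen, as were most genes of the test on a single library. The test on variation between single libraries was not, but its list of nuclear-retained transcripts was written after the table had been examined. In 7 of 126 groups of 4 libraries, 1 library stood apart from the other 3, where chance gives about 6.3. Propionate replicate 2 was the highest of its group in the PPAR-alpha and fatty acid oxidation score, at -0.0093 against -0.191 to -0.166, and the lowest in the immediate early and heat shock score, at -0.347 against 0.07 to 0.09. It was also the highest of its group for Marchf10, at 157.5 scaled counts against 72.8 to 85.3, and for Slc6a19, at 9836 against 7922 to 8228. Control replicate 2 was the highest of its group for Pde6a, at 61.5 scaled counts against 42.1 to 45.0. Control replicate 3 was the highest for Mdk, at 3125 against 2481 to 2590, and propionate replicate 4 for Rpl19, at 7590 against 6387 to 6583.

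Short, GC-rich genes were higher and long ones lower with propionate, and the mean ribosomal protein score differed by 0.16 ± 0.04 (SE over libraries; exact permutation p = 0.0286) and by 0.184 ± 0.04 (exact permutation p = 0.0286) once the trend was removed. Selection on these libraries favours such p-values. The part that the fitted trend gave was -0.02 ± 0.02. Other listed genes of the same length and GC would give 22.1 of 32 members higher. The upper end of that range is 26 if genes were independent, where all 32 were higher. By this count the trend runs with the score. Removal also moved the share higher of all tested genes from 53.2% to 63.8%, so the -0.02 can hold a shift of whole libraries. Whether the trend, as fitted, is the whole cause therefore cannot be told from it. The fit used the deposited gene length, which was 6256 bases for Rps24 and 4685 for Rps19 but 1022 for Rpl19. Rpl19 itself went from 0.21 to 0.08 with the trend removed. A trend with the length of the expressed transcripts was not fitted, so it stays open as a cause. The correction did widen the differences of single members, from 0.08 to 0.26 before to -0.10 to 0.51 after, and it was fitted on selected genes, so it can also take away an effect of treatment. For respiratory chain genes the score was 0.19 ± 0.08 before and 0.173 ± 0.08 after (exact permutation p = 0.0857 both times). The fitted trend gave 0.01 ± 0.02 of it, or 6.61%, but the score passed neither before nor after, and the call of the list ended as 1 member turned and the share higher of all tested genes went from 53.2% to 63.8%, so the trend and treatment cannot be told apart. RNA handling that varies between libraries stays open too: within the groups the ribosomal score and that of nuclear-retained transcripts had r = -0.681 (exact permutation p = 0.155) and rho = -0.69 (exact permutation p = 0.191), with r = -0.16 without the 2 libraries farthest from the median, so the relation rests on those.

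Lipid metabolism genes were lower, 17 of 20 over both lists. A smaller share of proximal tubule cells would lower the other markers of this segment by about as much. Their score differed by 0.04 ± 0.08 (SE over libraries, 95% t interval -0.17 to 0.24), which lies above the lipid score by 0.399 ± 0.11 (0.12 to 0.68). This argues against a smaller share of the segment as a whole being the whole cause, though these markers moved both ways and had been selected on these libraries. A smaller share of only a part of the proximal tubule was not tested. The lipid score differed by -0.36 ± 0.10 (SE over libraries; exact permutation p = 0.0286) and by -0.218 ± 0.10 (exact permutation p = 0.0571) once the length and GC trend was removed. The call of the score ended because the difference shrank while its spread stayed, the list of PPAR-alpha and fatty acid oxidation genes, with 9 of 12 lower instead of 10, gained its call by Fisher's exact test only as more of the other genes were higher (adjusted p = 0.0385 against 0.0553, and 0.64 by camera with an estimated correlation), and the trend and treatment cannot be told apart for these genes. The part that the fitted trend gave was -0.15 ± 0.02, or 40.0% of the difference; judged by that part alone the trend would fall short of the whole, and this looser reading was set aside because the call of the score ended.

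Macrophage and monocyte genes were lower, 28 of 28 over the fixed list and a wider list written after the table was examined, but the groups overlapped: control replicate 2 had a score of -0.30 on the wider list, against 0.46 to 0.94 in the other controls and 0.03 and -0.18 in propionate replicates 1 and 3. Without each library in turn the median log2 fold change stayed at -0.74 or lower, but the genes had been selected on these libraries and most were picked once their direction was seen, so a single library as the source cannot be told apart from treatment by this. The myeloid score differed by -0.98 ± 0.37 (SE over libraries) and by -0.82 ± 0.36 once the length and GC trend was removed (exact permutation p = 0.0857 both times), so it did not pass either way, while the fixed list alone, with the same 5 lower, gained its call by Fisher's exact test (adjusted p = 0.0309 against 0.0556) and not by camera with an estimated correlation (adjusted p = 0.64). The fitted trend gave -0.16 ± 0.03 of it, and judged by that part alone it would fall short of the whole, but what is left did not pass, so with a spread between mice of this size the trend, chance and treatment cannot be told apart. A lower myeloid content with propionate may be a hypothesis to follow up, untested here by any count of cells.

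The real grouping of the 8 libraries gave 1216 genes by edgeR and the highest of the other groupings gave 5, so that 1 of 35 splits gave as many. The genes had been selected for the real grouping, which fixes this outcome, so whether chance can be excluded cannot be told from it.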

How the results depend on the processing

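Total-count scaling, limma-trend, removal of the length and GC trend, lists on genes with a deposited adjusted p under 0.05, camera with a preset correlation or on other settings, and every count adjusted over 16064 genes were chosen after the data were examined; the other alternatives were set before. The cause of each move was not tested unless stated. The count of 1216 genes adjusted over the listed genes became 771 with a mean of at least 50, 1859 with DESeq2, 576 with the trend removed, 157 in the authors' deposited table, 104 with an absolute log2 fold change of at least 1, 10 at an adjusted p of 0.01, and 148 to 1262 without 1 library. The count of 6 adjusted over 16064 genes became 0 with the authors' size factors (1690 at an unadjusted p under 0.05), total-count scaling (1654), limma-trend (1664) and an adjusted p of 0.01, 2 with limma without trend, 3 with no filter, 12 with library weights, 15 with a mean of at least 50, 172 with DESeq2, 109 with the trend removed, 157 in the authors' deposited table, 1 with an absolute log2 fold change of at least 1, and 0 to 12 without 1 library. Of the 109, 28 are among the 157. The 2 lists that passed became 4 with a mean of at least 50 and with protein-coding genes (PPAR-alpha and macrophage lists added), 3 with the trend removed (the same 2 added, oxidative phosphorylation lost), 3 with camera and a preset correlation (PPAR-alpha added), 6 without genes in more than 1 list (cholesterol and glycolysis lists also added), 5 with fry, which tests a list against no change and not against the other genes (PPAR-alpha, cholesterol, NRF2 and androgen lists added, oxidative phosphorylation lost), 0 with camera and an estimated correlation, also with the trend removed or without genes in more than 1 list, 0 on genes with a deposited adjusted p under 0.05 (few members left), and 2 to 2 without 1 library. The 16 leading genes became 10 with a mean of at least 50, 9 with an absolute log2 fold change of at least 1, 1 at an adjusted p of 0.01, and 8 to 15 without 1 library; propionate replicate 3 gave the 8 and control replicate 3 a 10. Aldh6a1 and Slc5a8 turned to 0.1214 and 0.0614 with the trend removed. For the 50 named genes, 694 values under other settings held 652 of the same call, 39 ended calls, 1 gained call and these 2 turns; of 400 values without 1 library, 117 ended a call, over 30 of the genes, at edgeR adjusted p-values of 0.0503 to 0.107. With the replicate number as a block, 1273 genes passed over the listed genes, 0 over 16064 genes (1468 at an unadjusted p under 0.05), 15 leading genes and 2 lists; same-numbered libraries correlated at 0.23, 0.25, 0.03 and 0.17, replicates 1, 2 and 4 were each other's best partners and both replicates 3 correlated best with replicate 1 of the other group; the sources used here give no pairing, so the main fit has no block. Other pseudocounts and edgeR on recovered reads were not run, since raw counts were used. At 20005328 to 26711127 reads, simulated 1.5-fold changes were called in 82% of genes over the simulated genes and 62% over 16064. The simulated genes had not been selected for a difference, so these shares do not hold for the genes analysed here.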

Other observations

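The tests in this part were chosen after the results were seen, and its lists were written after the table had been examined, with many members picked once their direction was known. Beside Slc6a19, other carriers of neutral and basic amino acids were higher with propionate. Its brush border partner Cltrn had a log2 fold change of 0.19 ± 0.06 (SE), the basolateral light chain Slc7a7 of 0.35 ± 0.10 and Slc38a2 of 0.33 ± 0.09, and these 3 rose in the authors' deposited table at adjusted p-values of 0.0326, 0.0337 and 0.015. Slc1a4 went the other way, with a log2 fold change of -0.53 ± 0.09 (SE), and fell at an adjusted p of 0.00251 in the authors' deposited table. In other segments, the calcium-binding protein S100g of the distal tubule went from 6483 ± 1333 to 9512 ± 665 scaled counts (SD, n = 4), and the kidney cadherin Cdh16 from 22938 ± 1034 to 27503 ± 2026. Both rose in the authors' deposited table, at adjusted p-values of 0.00827 and 0.0289.

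A shared rise of these amino acid carriers may be a hypothesis, but 6 of 7 tested members were higher and Fisher's exact test of their direction gave p = 0.13.

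Nuclear-retained and intron-retaining transcripts were lower in 21 of 21 tested members, Xist among them. Malat1 ranged from 6379 to 9112 scaled counts in controls and from 2879 to 6080 with propionate. Their score differed by -0.49 ± 0.14 (SE over libraries; exact permutation p = 0.0286) and by -0.112 ± 0.08 (exact permutation p = 0.2) once the length and GC trend was removed. That trend gave -0.38 ± 0.07 of the difference and could account for this group, though other listed genes of the same length and GC would give 17.9 lower, with 20 as the upper end of the 95% range if genes were independent.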
